A study of Gallus gallus with 4 samples.

How the data were processed

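RNA sequencing counts were analysed from 4 libraries of whole chick (Gallus gallus) embryos. Embryos had been treated at Hamburger-Hamilton stage 8 with thalidomide at 40 µg/ml, with spermine NONOate at 10 µM, with both, or with the solvent DMSO, and were collected on day 6. Each condition has 1 library. Whether a library holds 1 embryo or a pool, and the sex of the embryos, are not given in the sources used here.

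Total RNA was extracted with Trizol and prepared by standard Illumina methods, per the labels' protocols, and sequenced on an Illumina HiSeq instrument, per the submitters' design text. The submitters' processing notes name TopHat2 version 2.0.8, the chicken genome build galGal4 and DESeq. The annotation was Ensembl release 75, per the file headers. The counting tool, its version and its use of strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart, and reads of near-identical gene copies can be split between them. Values of haemoglobin, ribosomal protein, ENS-1, ERNI and DMB2 genes are uncertain for that reason. The deposited table holds the authors' raw read counts per gene for the 4 libraries. It also holds the authors' fold (ratio), log2 fold and p-value for each of 5 comparisons. The p-values in the authors' deposited table are used here as counts under 0.05 without adjustment, and its folds only for their direction.

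The table used has 13081 genes on chromosomes 1 to 21. Of these, 10630 carry a gene symbol and 2451 carry a biotype, a date or a bare identifier in its place. Genes of chromosome Z and of the mitochondrial genome were not analysed here. A symbol borne by several genes was kept for the gene with the most reads. The NCBI RefSeq table of assembly GRCg7b served for names alone: it linked 16 list members to an older symbol.

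Counts were scaled between libraries with TMM (edgeR 4.0.16, R 4.3.3) and are given as normalised read counts (CPM). With 1 library per condition there is no replicate spread, so no p-value was computed for any comparison of 2 libraries. A gene was called higher or lower by a rule of size: at least a 2-fold ratio with 0.5 reads added to each count, at least 20 reads in the higher library, and a 95% exact conditional-binomial (Clopper-Pearson) interval of the ratio that excludes 1. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Where a library had 0 reads, the fold is a lower bound against a floor of 3 counts in that library. On simulated Poisson counts for thalidomide against control, over 13081 genes, the rule recovered 99% of 200 genes changed 2.5-fold and 99.5% of 200 genes changed 4-fold. It called 15 and 16 unchanged genes. Poisson counts hold no spread between embryos, so these are not false-call counts for real libraries.

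Gene lists for tissues, pathways and complexes, 37 in all, were fixed before the data were examined, as were the rule of size, the genes to name and the other settings to try. They held 920 members by name, of which 649 were found by symbol; 104 more came from family patterns. A list's median log2 ratio was ranked among 10000 random lists of the same size matched on mean expression in 20 bins, over members with at least 20 reads in total. A list was said to stand apart under percentile 2.5 or over 97.5. This describes these libraries and is not a test of the conditions. Of the lists, 36 could be ranked, and 1.8 would stand apart by chance.

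The genes named are, per comparison, the 8 highest and 8 lowest by the interval bound nearest to no change (symbol, at least 100 reads in the higher library), up to 4 members of each list that stood apart or had 3 or more members called, and a set of thalidomide and nitric oxide genes; some genes this rule names are not reported here. For the factorial fit they are the 5 smallest adjusted p in each direction. HBZ, and the lists of short mRNAs, long mRNAs, further hepatocyte genes and further red blood cell genes, were added after the data were seen.

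The 2 by 2 layout was also fitted with edgeR's quasi-likelihood F test, with the 2 treatments additive on the log scale, which leaves 1 residual degree of freedom. Genes needed at least 20 reads in at least 2 libraries. Calls had a Benjamini-Hochberg adjusted p under 0.05. Any interaction counts as spread in this fit, and it is not a test over biological replicates. Standard errors are the log2 fold divided by the root of F. On simulated counts for the thalidomide effect the fit recovered 48.5% of 200 genes changed 2-fold among 12074 and 99% of 200 changed 4-fold among 12072, with 12 unchanged genes called each time.

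Comparisons that share a library share its chance values. Unchanged libraries were therefore simulated 100 times, as Poisson counts and as negative binomial counts with the common dispersion of the 4 libraries taken as 1 group (coefficient of variation 0.324). The latter treats all differences between the libraries as spread, so it is an upper reference. Alternatives tried were other scalings (DESeq2 1.42.0 size factors, total counts, upper quartile, totals without the 50 most abundant genes), other read minimums, folds and interval rules, thinning to the shallowest library, 5 reads added, 200 reads per list member, means for medians, and for the factorial fit DESeq2, no filter, no robust step and other terms. Total counts in the factorial fit were added after the data were seen.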

Results

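Whole-embryo transcriptomes were measured by RNA sequencing in day 6 chick embryos treated at Hamburger-Hamilton stage 8. Thalidomide is a teratogenic drug that binds cereblon, the substrate receptor of a ubiquitin ligase. Spermine NONOate releases nitric oxide in solution. The series asks how nitric oxide modulates the transcriptome of thalidomide-treated embryos. Each of the 4 groups has 1 library: control (DMSO), thalidomide, spermine NONOate, and thalidomide plus spermine NONOate, called the combination. They held 79359076, 66889240, 62576258 and 72309065 reads in genes, in that order, and 12859, 12915, 12863 and 12934 genes had a read. No difference between conditions has a replicate check. Every value compares libraries, with counting intervals at 95%.

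The first comparison asks what thalidomide alone changed. Red blood cell and lens genes were lower in the thalidomide library than in the control library. HBAA, an alpha haemoglobin, was 9.39-fold lower (log2 -3.23, interval -3.24 to -3.22), and CRYAA, the alpha crystallin of the lens, was 9.80-fold lower (log2 -3.29, -3.40 to -3.19). Ribosomal protein genes were lower as a group, while in the kidney list 8 of 19 genes were higher and 3 lower. By the rule of size 1131 genes were higher and 875 lower, of 12138 with 20 reads in either library. Simulated unchanged libraries gave on average 5.78 higher and 6.16 lower calls as Poisson counts. As negative binomial counts, the upper reference, they gave 886 and 886. How many of the observed calls reflect spread between embryos cannot be told from 1 library per group.

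The genes furthest above control included MUC4, a membrane mucin (log2 8.91, 7.58 to 11.41, from 1626 against 3 reads), and C12ORF59 (log2 5.20, 3.84 to 7.72, against 3 reads). SLC13A1, a sulfate transporter, had 116 reads against 0, which is at least 40.1-fold higher. ENS-1 and ERNI, members of a repeated chicken gene family whose copies can share reads, were higher by log2 4.75 (4.46 to 5.07) and 4.61 (4.38 to 4.85). SLC51A, a subunit of a bile acid and steroid transporter, A1CF, a cofactor of apolipoprotein B mRNA editing, and AIRE, a transcriptional regulator, were higher by log2 4.14, 4.05 and 4.20. The genes furthest below control were UPK3A, a uroplakin of urothelium (log2 -5.08, -5.44 to -4.75), RHAG, a red cell membrane protein (-4.65, -5.10 to -4.25), the chemokine gene CCLI10 (-4.63), SERPINA1, which encodes alpha-1 antitrypsin (-4.73), DMB2 (-3.80) and the tendon gene TNMD (-3.44).

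Of the 36 ranked lists, 13 stood apart in thalidomide against control, 10 below and 3 above. Erythroid genes had a median log2 ratio of -1.89, with 8 of 12 members lower, among them RHAG, HBAA, HBAD (-3.18) and HBG2 (-2.79). HBZ, an embryonic haemoglobin, had a log2 ratio of 0.10. Lens genes had a median of -2.18, with 10 of 15 lower, including ASL1, the delta crystallin gene (-2.56), CRYBA4 (-2.52) and CRYBB3 (-2.42). Among cytosolic ribosomal proteins 26 of 52 were lower (median -0.998), for instance RPS27A (-1.53), RPLP1 (-1.48) and RPS20 (-1.46). In nuclear-encoded oxidative phosphorylation 8 of 42 were lower (median -0.72), such as NDUFB2 (-1.36). Beside these groups, a list of 80 short mRNAs of other cell machineries had a median of -0.48 with 75 members below 0, 62 short mRNAs of mitochondrial ribosome and import a median of -0.54 with 61 below 0, and 59 long mRNAs a median of 0.99 with 58 above 0. The short and long lists were added after the data were seen. The mRNA lengths themselves were not used here, so single members were not checked for length.

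Skeletal muscle genes were also below random lists (median -0.79, 9 of 26 lower), including CAV3 (-2.30), the fast troponin gene TNNI2 (-2.20) and the myosin light chain gene MYL1 (-2.17). The oxidative stress list had a median of -0.56 with 5 of 24 lower: the ferritin gene FTH1 (-1.37), GPX3 (-1.35), HMOX1, the inducible haem oxygenase (-1.31), and NQO1 (-1.27) were the largest. That median is close to those of the short mRNA lists in this comparison (-0.48 and -0.54). Random lists were not matched on mRNA length, so a change particular to oxidative stress genes was not separated from that trend. The same limit holds for the other lists of this comparison. The lists for retina and pigment cells (-0.67), gonad and germ cells (-0.62), leukocytes (-0.52) and limb (-0.30) stood apart below as well. Limb did so only by its median and not by its mean (-0.14). The combination against spermine NONOate shares no library with this comparison. There skeletal muscle (-0.07), retina (-0.23), gonad (-0.19), leukocytes (0.004) and limb (0.19) did not stand apart, while oxidative stress did (-0.66). In the limb list 5 genes were higher and 4 lower. SHH, which encodes a morphogen, was higher (log2 1.84, 1.70 to 1.99), as was FGF8 (1.57). SALL4, a zinc finger protein that cereblon recruits in the presence of thalidomide, was higher too (1.33, 1.22 to 1.44), while FGF4 was lower (-1.44). The libraries hold whole embryos, so a change in limb was not separated from other tissues. SHH and FGF8 also lay above the same control library with spermine NONOate alone, FGF8 short of the rule under TMM scaling. Above random lists were kidney (0.61, with 8 of 19 higher and 3 lower), smooth muscle (0.38, where RGS5 was the only member called, and it was lower at -1.73) and cholesterol synthesis (0.36, none called). Smooth muscle did not stand apart by its mean (0.15), nor cholesterol synthesis when members needed 200 reads. Kidney (0.16) and cholesterol synthesis (0.23) did not stand apart in the combination against spermine NONOate. Liver and yolk sac endoderm did not stand apart (median -0.20, percentile 7.59) and was mixed, with 8 of 34 higher, such as LRP2 (2.51) and HNF4A (2.51), and 8 lower, such as FETUB (-2.68).

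Of the nitric oxide and cyclic GMP list 6 of 20 were higher and 1 lower in the thalidomide library (median 0.30), and the list did not stand apart. The largest were GUCY1A2 (1.87) and the cationic amino acid transporter SLC7A2 (1.37) above control, ASS1 (-1.36) below it, and NOS2, the inducible nitric oxide synthase, above it (1.17, 1.08 to 1.26). CRBN, which encodes cereblon, had a log2 ratio of 0.40, NOS1 -0.82, VEGFA 0.44, KDR 0.25, PRKG1 0.37 and GUCY1A3 -0.26, all short of the rule. In other lists that did not stand apart, WNT signalling had 6 of 27 lower, including SFRP2 (-1.80) and WNT6 (-1.53), and the BMP antagonist gene NOG was lower (-2.27).

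Scaling sets how many of these genes were called lower. With libraries scaled to total counts the median of all genes moved by 0.20 (log2), and the share of higher genes among those called went from 56.4% to 74.9%. In the authors' deposited table, at an unadjusted p under 0.05, 422 genes were higher and 224 lower.

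**Figure D1:**
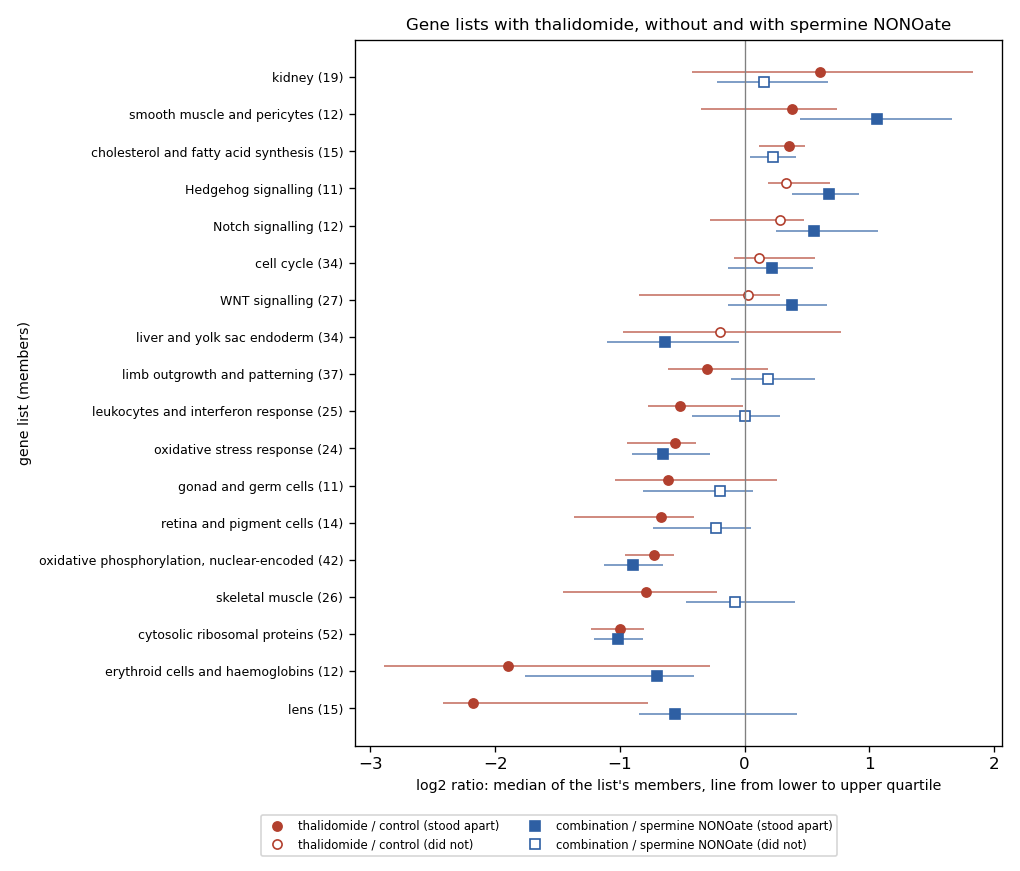
Median log2 ratio of each gene list (x axis) for thalidomide against control (red circles) and the combination against spermine NONOate (blue squares), with lines from the lower to the upper quartile of the members; filled symbols stood apart from random lists in that comparison. Ribosomal proteins lie at -0.998 and -1.02, and lens genes at -2.18 and -0.55.

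Spermine NONOate alone was set against control, and the plasma protein genes of liver and yolk sac were higher in its library. ALB, which encodes serum albumin, was 9.63-fold higher in the spermine NONOate library (log2 3.27, 3.22 to 3.31), and 31 of the 34 liver and yolk sac genes were higher, with none lower (median 2.33). Kidney genes were higher too (8 of 19, median 0.61), and MYH11, the smooth muscle myosin heavy chain, was 6.92-fold lower (log2 -2.79, -2.84 to -2.74). In all, 530 genes were higher and 156 lower, of 12066.

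SERPINC1, the antithrombin gene, was higher by log2 3.27, the clotting factor gene F9 by 3.23 and APOH by 3.01. Other genes far above control were ACSM4 (5.55, 5.06 to 6.12), SUSD2 (4.17), A1CF (3.97), XDH, which encodes xanthine dehydrogenase (3.86), SLC7A13 (3.62) and TM4SF4 (3.54). C12ORF59 was at 5.43 (4.06 to 7.94, against 3 reads). In the kidney list SLC34A1, a phosphate transporter (3.15), and SLC12A1 (1.74) were among those higher. A further list of 39 hepatocyte enzymes, transporters and transcription factors, added after the data were seen and sharing no member with the fixed liver list, had a median of 1.93 with 29 higher and none lower.

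UPK3A was lower in this library as well (log2 -4.61, -4.94 to -4.31), followed by the neuromedin receptor gene NMUR1 (-3.34), ADIPOQ, which encodes adiponectin (-3.39), GPRC5A (-2.69), KK34 (-2.52), TRIM66 (-2.12) and B3GNT7 (-2.05). In the smooth muscle list 4 of 12 were lower (median -0.71): MYH11, ABCC9 (-1.61), MYOCD, a smooth muscle transcription coactivator (-1.55), and MYLK (-1.44). In all 19 lists stood apart, 15 below and 4 above. Besides liver and kidney, neurons lay above (0.55, with 5 of 26 higher, such as DBH at 1.31 and SCG2 at 1.30). Oxidative phosphorylation also ranked above, at a median of 0.01 with no member called, though not by its mean. Lens genes lay below (-0.81, with 3 of 15 lower, including CRYBA1 at -1.13), as did leukocytes (-0.39, with 1 of 25 higher and 4 lower: MARCO at -1.75 and the complement genes C1QA, C1QC and C1QB at -1.60, -1.47 and -1.24) and limb (-0.41, 1 of 37 higher and 3 lower, with HOXA13 at -1.93 and SHH higher at 1.07). The other lists below had medians from -0.35 to -0.18 and at most 1 member called, among them WNT, Notch and Hedgehog signalling, cell cycle and connective tissue matrix. Hedgehog signalling did not stand apart by its mean. The lists of short and long mRNAs also stood apart here, at 0.02 (percentile 99.85) and -0.21 (percentile 0.03). Medians of that size were not separated from this trend.

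The erythroid list had no member called with spermine NONOate alone (median -0.02), nor had ribosomal proteins (-0.09). Of the nitric oxide genes NOS2 had a log2 ratio of 0.52, NOS1 -0.20, GUCY1A3 0.53, PRKG1 -0.33 and HMOX1 -0.32. CRBN was at -0.17, SALL4 at -0.15, FGF8 at 0.97, VEGFA at 0.28 and KDR at 0.10; none passed the rule. FGF8 passed it at 1.03 with total counts and also under upper quartile scaling or without the 50 most abundant genes. The authors' deposited table had 466 genes higher and 121 lower at an unadjusted p under 0.05 in this comparison.

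The combination was also set against control. Liver and yolk sac genes were higher (23 of 34, median 1.46) and kidney genes too (9 of 19, median 0.90), while ribosomal protein genes (31 of 52, median -1.06), lens genes (11 of 15 lower and 1 higher, median -1.41) and erythroid genes (5 of 12 lower and 1 higher, median -0.95) were mostly below control. ERNI was 39.1-fold higher (log2 5.29, 5.07 to 5.53) and HBAA 4.82-fold lower (-2.27, -2.28 to -2.26). In all, 1239 genes were higher and 499 lower, of 12176.

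Among the highest were ENS-1 (log2 5.48), A1CF (5.33), SUSD2 (5.16) and ACSM4 (5.05), and MUC4 (5.61, 4.26 to 8.12, against 3 reads). SLC13A1 was at least 77.0-fold higher, with 245 reads against 0. HNF4A (3.56) and MTTP, which loads lipid onto lipoproteins (3.25), were also higher. UPK3A (-4.36), CCLI10 (-4.14), TSPAN10 (-3.68), RHAG (-3.00), UCN3 (-2.90), CCLI7 (-2.61) and SERPINA1 (-2.55) were lowest. Lists above random lists included neurons (0.38, with DCX at 1.92), neural progenitors (0.45, with PAX2 at 2.30), endothelium (0.43, 1 of 21 higher and 1 lower), Notch signalling (0.42, none called), Hedgehog signalling (0.47, with SHH at 1.49 and GLI3 at 1.32) and nitric oxide signalling (0.39, with 4 of 20 higher, GUCY1A2 at 2.15, PDE5A at 1.15 and PDE3A at 1.12 among them). Oxidative phosphorylation (-0.90, 8 of 42 lower) and oxidative stress (-0.55, with HMOX1 at -1.45 and GPX7 at -1.23) were below, as were leukocytes (-0.58), gonad (-0.57) and skeletal muscle (-0.27, 5 of 26 lower). Retina (-0.34, 1 of 14 higher and 1 lower), heart muscle (-0.30, 4 of 22 higher and 3 lower) and limb (-0.23, 4 of 37 higher and none lower) ranked below by the median, but did not stand apart by the mean or when members needed 200 reads. The list of 80 short mRNAs was at -0.69 here and the 59 long mRNAs at 0.94.

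SALL4 had a log2 ratio of 0.75 in the combination against control, NOS2 0.74, NOS1 0.46, CRBN 0.39, KDR 0.45, VEGFA 0.57, PRKG1 0.73 and GUCY1A3 -0.19, none past the rule, while FGF8 was higher (1.36). Scaling to total counts moved the median of all genes by 0.22 and the share of higher calls from 71.3% to 87.7%; without the 50 most abundant genes the figures were 0.12 and 81.6%. In the authors' deposited table, at an unadjusted p under 0.05, 499 genes were higher and 149 lower.

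The comparison of the combination with thalidomide alone asks what the nitric oxide donor changed in thalidomide-treated embryos. Liver and yolk sac genes were again higher, 25 of 34 with none lower (median 1.68): ALB by 11.9-fold (log2 3.58, 3.48 to 3.68), FETUB by log2 3.24, F9 by 3.13 and AMBP by 3.02. Part of the thalidomide difference in red cell and lens genes was smaller in the combination, with RHAG (log2 1.65, 1.19 to 2.15), SPTB, the red cell spectrin gene (1.17), HBG2 (1.03), CRYAA (1.74, 1.62 to 1.85), CRYBA4 (1.23) and ASL1 (1.16) higher than with thalidomide alone. In all, 454 genes were higher and 151 lower, of 12154.

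HRG (log2 3.42), NME4 (3.79), CL2 (3.25), the vitamin D binding protein gene GC (2.91) and TAP2 (3.54) were also among the highest. Among the lowest were MUC4 (-3.30, -3.53 to -3.08), SLC51A (-2.17), UCN3 (-2.20), NEK3 (-1.83), SPAG16 (-1.82), CP450CC24 (-1.55) and ASTL (-1.46). Lists above were liver, erythroid (0.71, with 3 of 12 higher), lens (0.70, with 3 of 15 higher), skeletal muscle (0.48), retina (0.47), Notch (0.32), cartilage (0.31), neurons (0.30) and matrix (0.26), the last 6 with at most 1 member called each. Below were cell cycle (-0.34), cholesterol synthesis (-0.31) and heart muscle (-0.24), none with a member called. NOS1 was higher (1.28, 1.09 to 1.48); NOS2 had a log2 ratio of -0.43, SALL4 -0.58, FGF8 -0.21, CRBN -0.01, HMOX1 -0.13, VEGFA 0.12, KDR 0.20, PRKG1 0.37 and GUCY1A3 0.07. The authors' deposited table had 392 genes higher and 199 lower at an unadjusted p under 0.05.

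**Figure D2:**
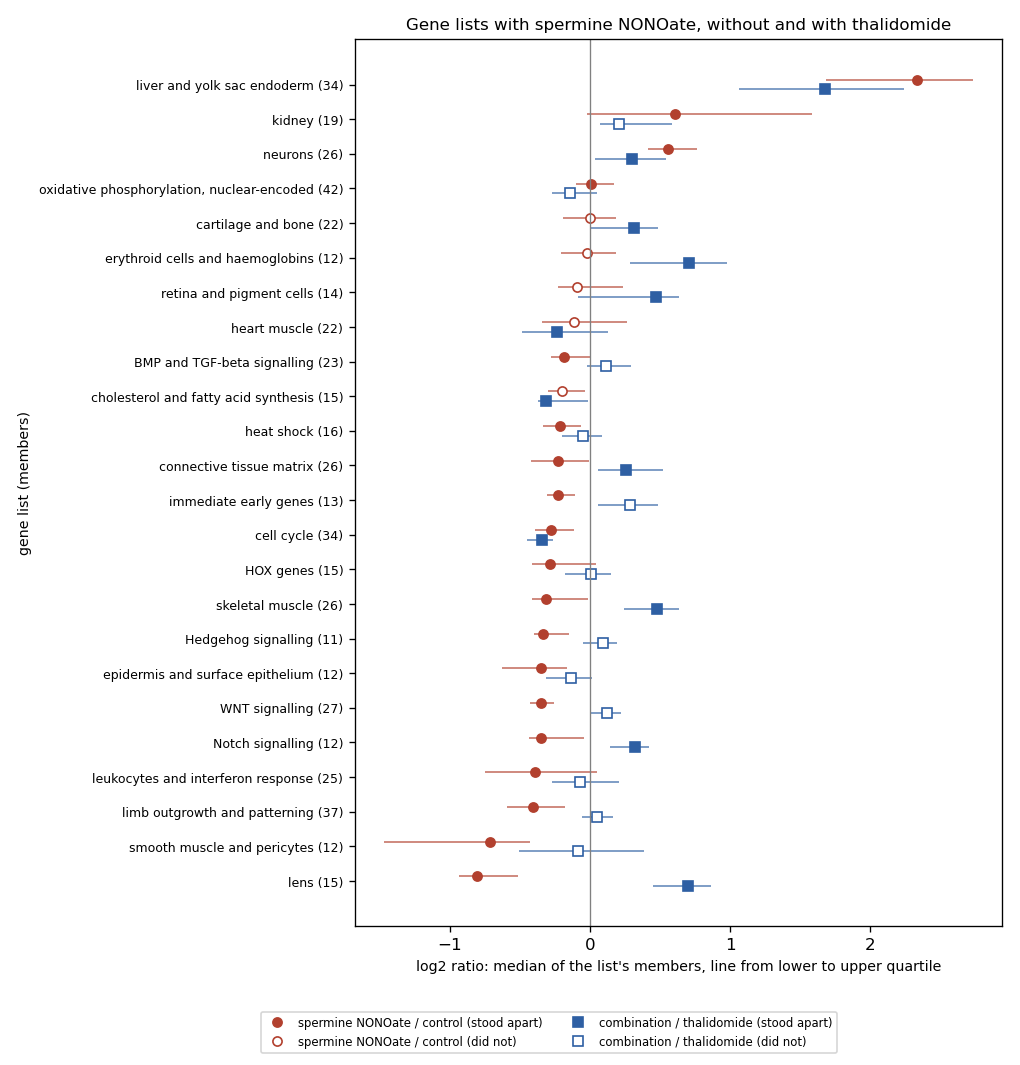
Median log2 ratio of each gene list (x axis) for spermine NONOate against control (red circles) and the combination against thalidomide (blue squares), with lines from the lower to the upper quartile of the members; filled symbols stood apart from random lists in that comparison. Liver and yolk sac genes lie at 2.33 and 1.68, and lens genes at -0.81 and 0.70.

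Of the 1131 genes higher with thalidomide, 780 (69.0%) were still higher in the combination than in control, and 79 (6.98%) were lower in the combination than with thalidomide alone. Of the 875 genes lower with thalidomide, 311 (35.5%) were still lower and 193 (22.1%) moved back up, RHAG, HBG2 and CRYAA among them. The shares that moved back changed with the settings. For higher genes they were 3.55% with a minimum of 100 reads and 10.6% at 4-fold. For lower genes they were 18.7% with a minimum of 100 reads and 29.5% with total counts. The comparisons behind these shares have libraries in common. Independent lists would share 106 and 36.2 kept genes, and 14.2 and 27.5 moved back. In simulated unchanged libraries 12.3% (Poisson) and 22.4% (negative binomial) of higher genes and 17.5% and 35.5% of lower genes moved back, so neither observed share exceeded the negative binomial reference. The kept shares were 15.9% and 35.3% in simulation for higher genes, and 11.9% and 22.4% for lower genes. The covariance of the log2 ratios of thalidomide against control and of the combination against thalidomide was -0.163, against -0.00733 (Poisson) and -0.238 (negative binomial) in simulation, so part of these shares may lie in the shared library. Over the same genes the combination against spermine NONOate, which shares no library with thalidomide against control, had a median log2 ratio of 1.07 where thalidomide against control had 1.36, and of -0.74 where it had -1.33.

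The combination against spermine NONOate measured thalidomide a further time, in the presence of the donor. Ribosomal protein genes (26 of 52 lower, median -1.02), oxidative phosphorylation genes (16 of 42 lower, median -0.90) and erythroid genes (5 of 12 lower and 1 higher, median -0.70) were below, liver and yolk sac genes were mostly below (12 of 34 lower and 2 higher, median -0.63), and smooth muscle genes were above (6 of 12 higher, median 1.06). The smooth muscle list was at 0.13 in the combination against control and -0.08 against thalidomide alone, standing apart in neither. It was low in spermine NONOate against control (-0.71), so its value here rests largely on the spermine NONOate library. In all, 1183 genes were higher and 742 lower, of 12161, and 11 lists stood apart. Scaling to total counts moved the median of all genes by 0.16 and the share of higher calls from 61.5% to 77.7%. The short mRNA list was at -0.72 (76 of 80 below 0) and the long mRNA list at 1.10 (59 of 59 above 0). In the authors' deposited table, at an unadjusted p under 0.05, 407 genes were higher and 217 lower.

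The contrasts that share no library overlapped. Of genes higher with thalidomide, 603 were higher in the combination against spermine NONOate too, where independent lists would share 105; of lower genes 270 were shared against 50.1, and 12 and 8 went opposite ways. Across 12090 genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.652. Both contrasts carry the trend of short and long mRNAs (medians -0.48 and 0.99 with thalidomide alone, -0.72 and 1.10 with the donor present), and its part in this overlap was not separated. For spermine NONOate, with and without thalidomide, 196 genes were higher in both against 17.9 for independent lists, 13 were lower in both against 1.18, and r was 0.231. A further 19 were higher without thalidomide and lower with it (4.23 for independent lists), and 9 lower and then higher (4.98). For thalidomide and spermine NONOate, each against the same control library, 173 genes were higher in both and 53 lower in both, while 7 were higher with thalidomide and lower with spermine NONOate and 45 the reverse. Independent lists would share 39.7 and 11.4 in the same direction, and 13.2 and 34.2 in opposite ones, and simulated unchanged libraries shared 0.94 and 0.62 (Poisson) or 311 and 196 (negative binomial). The covariance was 0.112, against 0.00702 and 0.237 in simulation, so part of this overlap may lie in the shared control. Control cannot be split, having 1 library. UPK3A was lower in each treated library.

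The additive factorial fit pooled the 4 libraries. For thalidomide edgeR's quasi-likelihood test called 2040 genes higher and 1718 lower of 12090; for spermine NONOate it called 193 higher and 15 lower. Scaled to total counts, chosen after seeing the data, the thalidomide split was 2872 and 973. Both thalidomide contrasts averaged here carry the trend of short and long mRNAs given above, so these counts and the list counts below include it. ERNI (log2 4.69 ± 0.26 SE, adjusted p = 1.7e-18), ENS-1 (4.85 ± 0.28, adjusted p = 3.44e-18), SCUBE1 (2.53), NFAT5 (1.99) and TNRC6B (2.17) led the genes higher with thalidomide in 2 of 2 pairs of libraries. SERPINA1 (-5.23 ± 0.31, adjusted p = 6.17e-18), SPP2 (-2.35), ALB (-2.17), RHAG (-4.03) and FETUB (-2.48) led those lower. With spermine NONOate ALB (3.42 ± 0.20, adjusted p = 7.16e-18), FETUB (3.04), ADH1B, an alcohol dehydrogenase gene (2.57), CL2 (3.11) and ITIH2 (2.31) led those higher, and ABCC9 (-1.16 ± 0.20, adjusted p = 0.000213), MYLK (-1.05), B3GNT7 (-1.46), VWDE (-1.05) and ACTG2 (-0.72 ± 0.18, adjusted p = 0.0124) led those lower.

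Within lists, 50 of 52 ribosomal protein genes fell with thalidomide in the factorial fit (51 adjusted over the list alone), 37 of 42 oxidative phosphorylation genes (39 adjusted over the list alone), 14 of 24 oxidative stress genes (15 adjusted over the list alone) and 7 of 12 erythroid genes, with 2 rising (the same counts adjusted over the list alone). Smooth muscle genes had 7 of 12 higher and 2 lower, also when adjusted over the list alone. Their median was 0.38 in thalidomide against control, with 0 called higher by the rule of size, and 1.06 in the combination against spermine NONOate. The latter rests largely on low values in the spermine NONOate library. Of the liver and yolk sac list 26 of 34 rose with spermine NONOate (30 adjusted over the list alone), while with thalidomide 7 rose and 12 fell (7 and 13 adjusted over the list alone). Smooth muscle genes had 3 of 12 lower with spermine NONOate, the same count adjusted over the list alone, and kidney genes 3 of 19 higher (4 adjusted over the list alone).

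Non-additivity, the log2 ratio of combination to spermine NONOate minus that of thalidomide to control, was at or above 1 for 503 genes and at or below -1 for 565 of 12273, with no test possible. It was above random lists for 10 lists, among them lens (median 1.55, 12 of 15 members), erythroid (0.94, 5 of 12), smooth muscle (0.88, 4 of 12) and skeletal muscle genes (0.70, 7 of 26), and below them for 5, among them kidney (-0.76, 8 of 19, with 1 the other way) and liver and yolk sac genes (-0.64, 9 of 34, with 2 the other way).

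**Figure D3:**
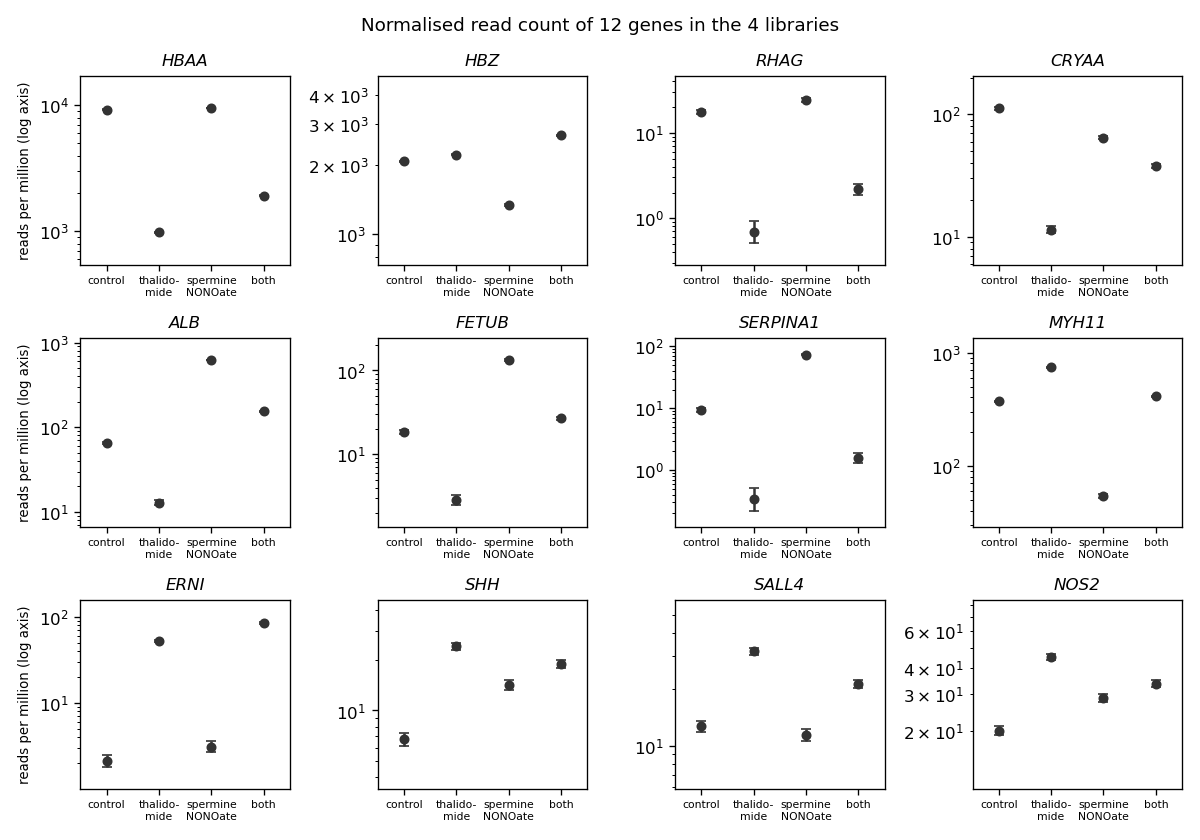
Normalised read counts (CPM, log axis) of 12 genes in the 4 libraries, 1 point per library with its 95% Poisson counting interval. HBAA, RHAG and CRYAA lie lowest in the thalidomide library, ALB and FETUB highest in the spermine NONOate library, and ERNI highest in the combination.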

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

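The effect of spermine NONOate went opposite ways without and with thalidomide for 4 lists, each standing apart below random lists in spermine NONOate against control and above them in the combination against thalidomide. The difference between arms was not tested, since each arm has 1 library per condition. It was 1.55 (log2, median non-additivity) for lens genes, whose medians were -0.81 and 0.70. The values were 0.70 for skeletal muscle (-0.31 and 0.48), 0.56 for Notch signalling (-0.35 and 0.32) and 0.54 for connective tissue matrix (-0.23 and 0.26).

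Genes called in opposite directions in the arms numbered 20 for thalidomide and 28 for spermine NONOate, also untested. With symbols among the former were TM4SF4 (log2 1.06 without and -2.19 with spermine NONOate), NYX (1.78 and -2.27), ARR3 (2.06 and -1.40) and CHRM5 (1.64 and -1.71); among the latter were MUC4 (3.99, interval 2.55 to 6.52 from 3 control reads, without and -3.30 with thalidomide), SLC51A (2.09 and -2.17), OXTR (-1.15 and 1.36) and TRIM66 (-2.12 and 1.48). These genes were picked after their values were seen.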

How the results depend on the processing

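Total counts in the factorial fit were chosen after seeing the data; the other alternatives were planned. Counts of genes moved by more than 1.5 times mainly with the threshold itself, by construction. Given as higher and lower, at a 1.5-fold threshold they were 2479 and 2265 (thalidomide against control), 1083 and 486 (spermine NONOate against control), 2542 and 1876 (combination against control), 1138 and 528 (combination against thalidomide) and 2544 and 2203 (combination against spermine NONOate). At 4-fold they were 208 and 138, 186 and 25, 237 and 51, 92 and 35, and 159 and 80 in that order. With the interval wholly beyond 2-fold they were 735 and 539, 321 and 62, 800 and 300, 225 and 54, and for the last the lower count was 450. A minimum of 100 reads gave 347 and 86 for spermine NONOate against control and 56 lower for the combination against thalidomide. Scaling to total counts left 560 lower with thalidomide, 255 lower in the combination against control and 468 lower against spermine NONOate; by construction this scaling shifts every gene of a library alike. Genes non-additive numbered 2958 at 1.5-fold and 216 at 4-fold. The percent moved back among genes higher with thalidomide was 5.20 with total counts, 3.55 with a minimum of 100 reads, 10.4 at 1.5-fold and 10.6 at 4-fold, and among lower genes 29.5, 18.7 and 26.2 for the first 3. The percent kept was 72.1 (total counts), 74.1 (1.5-fold) and 55.3 (4-fold) for higher genes and 30.4, 54.2 and 22.5 for lower genes; the cause was not tested. In the factorial fit the crossed split, control and combination against the single treatments, called 1 gene with spermine NONOate as a term and 3 with thalidomide as a term. In each of these fits the difference of the treatment left out counts as spread. The counts therefore give no false-call rate for the additive fit. Without thalidomide as a term edgeR called 0 genes for spermine NONOate (208 at an unadjusted p under 0.05; the thalidomide difference then counts as spread), against 182 by DESeq2 in the additive design; the range over the other alternatives was 172 to 237. Thalidomide calls ranged from 3289 to 3865. No list or named gene reversed under the alternatives run for it: the scalings for both, thinning for named genes and not lists, and 5 reads added, 200 reads and means for lists and not named genes. Among named genes and lists, total counts ended 21 calls, totals without the 50 most abundant genes 7, upper quartile 3 and thinning 2. With means in place of medians, limb and smooth muscle (thalidomide against control), oxidative phosphorylation, heat shock, immediate early genes, BMP and Hedgehog (spermine NONOate against control), limb, heart and retina (combination against control) and lens and WNT (combination against spermine NONOate) no longer stood apart. With 200 reads per member cholesterol synthesis (thalidomide against control) and limb, heart and retina (combination against control) did not. The correlation of thalidomide and spermine NONOate, each against control, was 0.232 over 12090 genes and 0.132 over 10272 genes with a mean of at least 200 reads. Simulated unchanged libraries, which share the control, gave 0.468 (Poisson) and 0.498 (negative binomial) over the 12090 genes. The smaller set was not simulated. Chance values of the shared control alone raise this correlation, so it does not show whether the treatments acted alike. The planned comparison of Z-linked genes and the list of mitochondrially encoded proteins were not run, because those chromosomes were not analysed here. Replicates could not be left out, and no library a reader may doubt can be dropped, with 1 per group. No paired analysis was possible because each group has 1 library. Depth limits genes of few reads: 11908 to 12054 genes had 20 reads in a library.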

Other observations

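In 3 patterns technical explanations were weighed. The tests of mRNA length, of scaling and of HBZ were chosen only after the result was seen; the tests of the further hepatocyte and red blood cell lists were set before their values were seen.

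Ribosomal protein and oxidative phosphorylation genes were lower in both thalidomide libraries. The ribosomal genes' highest median over the scalings was -0.80 in thalidomide against control and -0.85 in the combination against spermine NONOate. The scalings tried differ too little for this to have come out otherwise, so it decides nothing. Each scaling shifts all genes of a library alike. The ribosomal median therefore differed from that of all genes by -0.99 and -1.02 under every scaling. A general loss of short mRNAs is consistent with the values: 80 short mRNAs of other cell machineries had a median of -0.48 in thalidomide against control and -0.72 in the combination against spermine NONOate, both at percentile 0, while 59 long mRNAs lay at 0.99 and 1.10, both at percentile 100. In spermine NONOate against control these lists lay at 0.02 (percentile 99.85) and -0.21 (percentile 0.03), standing apart the other way. With thalidomide the short mRNAs' median is smaller than the ribosomal one (-0.998). Lengths were not used and the short list was not matched to the ribosomal genes, so how much of the size this trend covers cannot be told. The trend may come from RNA quality, fragment selection or the embryos, and with each library unreplicated a biological effect of thalidomide stays open and untested.

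Liver and yolk sac endoderm genes were higher in both spermine NONOate libraries. The lowest median over the scalings was 2.33 in spermine NONOate against control and 1.66 in the combination against thalidomide. Here too the scalings differ too little for another outcome, so this decides nothing. The list's median differed from that of all genes by 2.37 and 1.68 under every scaling. More liver or yolk sac tissue in these libraries is consistent with the further list of 39 hepatocyte enzymes, transporters and transcription factors, which had a median of 1.93 in spermine NONOate against control and 1.32 in the combination against thalidomide, both at percentile 100. Its most abundant members in control, GNMT and MASP1, were at 0.09 and -0.03 in spermine NONOate against control, and at 0.58 and 0.98 in the combination against thalidomide, none past the rule. Whether the tissue share came from dissection or from the treatment was not tested, and higher expression per cell stays open as well.

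Haemoglobin and erythroid genes were lower in both thalidomide libraries. The median of the 5 haemoglobin genes was -2.79 in thalidomide against control and -1.63 in the combination against spermine NONOate. Both lay below the 2.5th percentile of the medians of 10000 random sets of 5 short mRNAs (-0.77 and -1.06), so the drop was larger than that of those short mRNAs. This comparison was rewritten after its values were seen. The short mRNAs were not matched to the haemoglobin genes on length or expression, so it does not exclude a loss of short mRNAs as the cause. A loss of red blood cells of every kind alike would lower the haemoglobin genes together. HBZ was at 0.10 and 1.00 in these comparisons, against the medians of -2.79 and -1.63, which would exclude such a loss on HBZ alone. The criterion, rewritten after the values were seen, asks for at least 2 such genes in both. Its outcome was therefore known in advance and decides nothing. A single gene does not settle it either, so such a loss stays open. Fewer red blood cells may contribute: 18 further red blood cell genes had a median of -0.38 at percentile 2.29 in thalidomide against control. This was much smaller than the erythroid list's -1.89, and smaller than the -0.48 of the 80 short mRNAs. Random lists were not matched on mRNA length, so fewer red blood cells were not separated from that trend. The list's most abundant member, CA2, was at -0.08, and 2 members (CAT and BCL2L1) are also in other lists. The combination against control gave percentile 6.39 and the combination against spermine NONOate 3.5 (median -0.33), neither of which stands apart. A shift in the stage of red blood cells with thalidomide remains as an untested biological explanation.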
